A study of Mus musculus with 8 samples.

How the data were processed

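RNA of mouse embryonic fibroblasts (MEFs), the connective tissue cells that grow out of a dissociated embryo, was hybridised to 8 Affymetrix arrays. The cells were wild-type or lacked Smurf2, and came from the C57B6 background or from a mixed background of 129SVJ and NIH Black Swiss mice, here called mixed BL. Each combination was sampled at an early passage (7 in C57B6, 6 in mixed BL) and a late passage (28 in C57B6, 33 in mixed BL). Genotype, background and passage class therefore form a full factorial with 1 array per combination, 4 arrays at each level of each factor. Per the labels, the C57B6 cultures came from 1 embryo each, the Smurf2-/- mixed BL culture from a mix of 3 embryos and the wild-type mixed BL culture from a mix of 2. The labels give embryonic day 14.5 in the sample descriptions and day 11.5 in the growth protocol, and which holds is not known. They do not say whether the early and late arrays of a combination were passages of the same culture, nor the sex of any embryo, and per the series text there were no technical replicates.

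The deposited values are on a log2 scale and were centred by the authors on each transcript cluster's median over the 8 arrays, as the values show: the largest row median was 5e-07 in size. Scale was read from the single-precision step of the values, since 96.8% of the clusters held only whole multiples of the step of numbers from 4 to 8 (tolerance 6e-08), as log2 intensities have. The array normalisation and the probe summary behind these deposited log2 values are not given in the sources used here. The submitters' processing notes list the genome builds mm8 and mm9 without a role. The series text names an exon array, whereas the probe identifiers matched the annotation of a gene-level array of the same maker, and that annotation was used for names. Of 24169 transcript clusters, 19134 had 1 gene symbol, 1230 had several and 3805 had none; those with 1 symbol named 17501 genes, of which 899 had more than 1 cluster, Hmcn1 with 75. Symbols were updated through gene identifiers for 19067 clusters with a RefSeq gene table of assembly GRCm38.p6, used for names, neighbours and chromosome membership only, so no coordinates are given.

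Because each cluster was centred on its own median, the values hold no mean level to set clusters against each other, and their step gives only a coarse range. The planned filters on dim clusters could not be applied, and the planned mean-variance trend has no meaning on the mean of centred values. All 24169 clusters were therefore tested with limma without a trend, and the fit with a trend was kept as an alternative. The number of arrays limits the precision: 4 residual degrees of freedom remained in the additive model and 3 in the models with 1 interaction. The additive model held genotype, background and passage class. Interactions of genotype with passage and with background were each added in turn, and the contrasts within early or late passage, within a background and within a genotype came from those models. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The number that ends each sample title is the passage class itself, so the labels pair the arrays by passage class and the additive model holds that pairing; a fit without the replicate block was an alternative. A gene's value for the list tests and for Smurf2 was the mean of its clusters. For the list tests the plan had been the cluster with the highest mean, which has no meaning for centred values. Smurf2 and the sex-linked genes were also compared by exact permutation of 4 arrays against 4, for which the smallest two-sided p is 0.0286.

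The design, the alternatives, the gene lists and the naming rule were fixed before the data were examined, apart from the departures stated here. For genotype, passage and background the rule named up to 12 genes per direction with the largest change among clusters with 1 symbol that passed and had the same sign in all 4 matched pairs of arrays. Where fewer than 8 passed, genes of the smallest p with the same sign in all 4 pairs were added up to 8. They are given as values that did not pass. Up to 5 genes per direction were allowed for an interaction, filled to 3, and 4 members per gene list. Smurf2, Smurf1, Rnf20, Cdkn2a, Mdm2, Id1 and the sex-linked genes were always taken; Trp53, Cdkn1a and Ddx3y were not analysed here.

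A total of 25 gene lists were tested with camera at an inter-gene correlation of 0.01, with the correlation estimated, and with fry. They covered TGF-beta and Smad targets, BMP and Id targets, p53 targets, cell cycle, senescence and its secretory phenotype, DNA damage response and repair, H2B ubiquitination and chromatin modifiers, NEDD4 family ligases, extracellular matrix, interferon response, Wnt targets, oxidative stress (Nrf2), cholesterol synthesis, glycolysis and hypoxia, Hox genes and imprinted genes. Markers of macrophages and leukocytes, endothelium, epithelium and keratinocytes, neural and glial cells, skeletal muscle, adipocytes, cartilage and bone, and erythroid cells, and genes of the Y chromosome, made up the rest.

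Alternatives were quantile normalisation, gene means, no replicate block, all 3 interactions in the model, the culture (taken as each combination of genotype and background) as a random block, and leaving out each array in turn. The planned trend was fitted as an alternative, since the fit without a trend was adopted after the values were seen to be centred. Bright clusters alone, array medians set to 0, and a fit without X and Y clusters were added after seeing the data. Bright clusters were the 5331 (22.1%) at a log2 of 8 or more on all 8 arrays, as their step shows.

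The steps were tested on simulated data with 200 changed clusters among 24169. For genotype, passage and background, 74%, 72% and 74% of the clusters changed by a log2 of 1 were called, and 96%, 92% and 97% of those changed by 2. For the interactions of genotype with passage and with background, 8% of the clusters changed by 1 were called in both, and 62% and 57% of those changed by 2. Unchanged clusters made up between 1.41% and 5.56% of the calls. These shares hold for 200 changed clusters, since the adjustment of p-values is stricter where fewer clusters change. In the measured genotype fit, Xist at -4.36 had a limma adjusted p of 0.0517 and Thsd7a at 1.00 had 0.416. The simulated shares therefore cannot be read as the share of real changes called here. A cell cycle list shifted by 0.5 among 17501 genes was called with the preset correlation in every comparison. With the estimated correlation it was called for genotype, passage and background but for neither interaction. The simulated noise was independent between clusters, whereas the correlation estimated for the measured cell cycle list was 0.73 for genotype. These runs therefore cannot show that the preset correlation suits the measured lists. R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used, and figures were drawn with matplotlib 3.10.9.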

Results

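Gene expression was profiled in mouse embryonic fibroblasts with and without Smurf2, which encodes a HECT-type ubiquitin ligase of the NEDD4 family that marks Smad proteins and other targets for degradation. The 8 arrays were 4 wild-type and 4 Smurf2-/-, with 1 array for each combination of genotype, background (C57B6 or mixed BL) and passage class (early or late). Values are log2 differences from each transcript cluster's median over the 8 arrays, so levels of different genes cannot be set against each other. The labels do not say that the arrays were separate cultures throughout, and p-values measure only the spread between these arrays, which may be technical. The first principal component held 30.9% of the variance and placed the late Smurf2-/- arrays of C57B6 and mixed BL at 36.6 and 37.1, with the other 6 arrays below these.

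Smurf2 itself was lower in every Smurf2-/- array than in its wild-type partner. Averaged over its 2 transcript clusters, 10392259 and 10392261, it stood at -0.88 ± 0.38 (SD, n = 4) without and 0.69 ± 0.22 (SD, n = 4) with an intact gene, a log2 difference of -1.57 ± 0.12 (SE), or 2.97-fold. The matched pairs differed by -1.14 and -1.85 in C57B6 at early and late passage and by -1.67 and -1.62 in mixed BL. The exact two-sided permutation test gave p = 0.0286, the smallest possible, and limma an adjusted p of 0.0484 over 17501 genes. The permutation treats all arrays as exchangeable, although early and late arrays may be passages of the same culture. Tested as single clusters, the limma adjusted p was 0.0941 for 10392259 and 0.0517 for 10392261, with the same direction in all 4 pairs. Whether the probes lie in the deleted part of the gene is not known here.

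Sex-linked genes also separated the genotypes, by amounts not ranked against Smurf2 because the signal over background is unknown. Xist, the noncoding RNA that silences an X chromosome in female cells, stood at 2.52 ± 0.74 (SD, n = 4) in wild-type and -1.84 ± 0.23 (SD, n = 4) in Smurf2-/- arrays, 20.5-fold apart with a log2 difference of -4.36 ± 0.33 (SE). The Y-linked genes Uty and Kdm5d, of the histone demethylase families, were higher in Smurf2-/- by 2.35 ± 0.13 (SE, 5.09-fold) and 2.27 ± 0.14 (SE, 4.83-fold). Eif2s3y, a Y-linked translation initiation factor subunit, was higher by 3.50 ± 0.25 (SE, 11.3-fold). Each of these genes had the same sign in all 4 matched pairs and an exact permutation p of 0.0286. That p takes the arrays as exchangeable, which does not hold if early and late arrays share a culture. The limma adjusted p was 0.0268 for Uty and 0.0380 for Kdm5d, which passed, and 0.0517 for both Eif2s3y and Xist, which did not. The labels give no embryo sex, and the same 4 arrays stand against the same 4 in every genotype difference reported here.

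**Figure D1:**
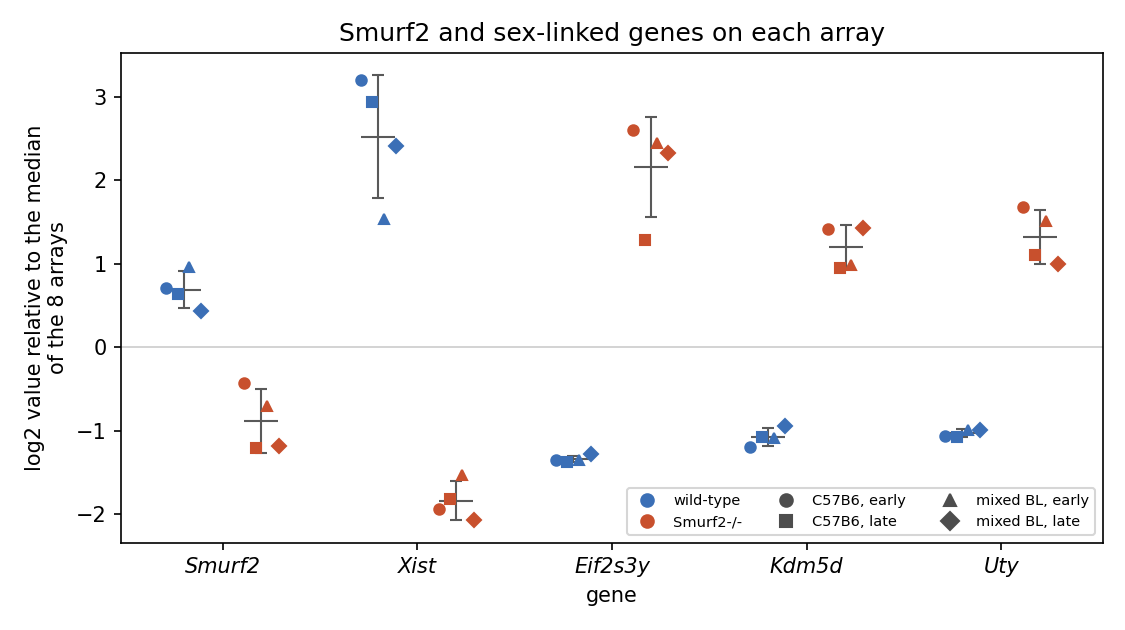
Log2 value relative to the median of the 8 arrays for Smurf2 (mean of its 2 clusters), Xist, Eif2s3y, Kdm5d and Uty; points are arrays, coloured by genotype and shaped by background and passage class, and bars are the mean ± SD of 4 arrays. The 4 Smurf2-/- arrays lie below the 4 wild-type arrays for Smurf2 (means -0.88 and 0.69) and Xist (-1.84 and 2.52), and above them for the 3 Y-linked genes.

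The genotypes were compared first across backgrounds and passage classes. Beyond Smurf2 and the sex-linked genes no named gene passed the test, and the closest were these. Fas, the death receptor and a p53 target, differed by -0.93 ± 0.11 (SE, n = 4 against 4), Plscr2, a phospholipid scramblase, by -1.28 ± 0.16, and Sardh, sarcosine dehydrogenase, by -0.75 ± 0.11. Myorg, Kank1 and Man2b2 differed by -0.48 ± 0.07, -0.59 ± 0.09 and -0.50 ± 0.08. On the positive side, Thsd7a differed by 1.00 ± 0.12, the folate enzyme gene Mthfd1l by 0.57 ± 0.10, the transporter gene Slc6a17 by 0.64 ± 0.11, the Myc target Cdca7 by 0.56 ± 0.10 and Gcsh of the glycine cleavage system by 0.31 ± 0.05. All had the same sign in 4 of 4 pairs, as the naming rule required, with limma adjusted p between 0.416 and 0.675. Of genes chosen for their known links to Smurf2, the H2B ubiquitin ligase gene Rnf20 differed by -0.08 ± 0.12, its paralog Smurf1 by 0.17 ± 0.13, Cdkn2a by 0.23 ± 0.18, Mdm2 by -0.25 ± 0.30 and Id1 by -0.66 ± 0.25, none called.

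Limma called 3 clusters for genotype, all higher in Smurf2-/-: Uty, Kdm5d and 10608138, a cluster without a symbol, at 4.34 ± 0.24 (SE, 4 of 4 pairs), chosen after its values were seen. By identifier 10608138 follows the clusters of the Y-linked genes, so it may be Y-linked, and the fit without X and Y clusters kept it. An unadjusted p under 0.05 was found for 1749 clusters, where 1208.4 are expected if p-values are spread evenly. This is no measure of an excess due to genotype. Of 33 ways to part the same arrays, 7, the real one included, gave as many, and the highest other gave 3964. Over gene means, 5 of 17501 genes were called: Uty, Kdm5d and Eif2s3y higher, Smurf2 and Xist lower. No call remained without the X and Y clusters, after quantile normalisation, with all interactions in the model, or without any 1 array other than late C57B6 Smurf2-/-; without that array 2 clusters were called, 1 of them among the 3; without the replicate block, that is without pairing by passage class, 5 were called. Within early passage limma called Uty alone, at 2.62 ± 0.10 (SE, adjusted p = 0.0422, higher in both early pairs), with 251 clusters at an unadjusted p under 0.05. The count was 2 without the late Smurf2-/- array of either background and 0 without any other array. Within late passage, C57B6 and mixed BL limma called 0, with 3030, 1475 and 892 clusters at an unadjusted p under 0.05; in mixed BL 2 were called without either the early or the late C57B6 Smurf2-/- array.

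Cell cycle genes lay higher without Smurf2 in every one of the 34 measured members, with a median log2 difference of 0.45. The mitotic kinase genes Aurka and Bub1b differed by 0.64 ± 0.17 and 0.66 ± 0.20 (SE), cyclin Ccnb2 by 0.84 ± 0.27 and the replication licensing factor Cdt1 by 0.65 ± 0.21, each in 4 of 4 pairs and none past the test. DNA damage response and repair genes were higher in 21 of 23 members, median 0.34, with Fanca of the Fanconi anaemia core complex at 0.52 ± 0.09 and the nuclease gene Mre11a at 0.54 ± 0.17. Glycolysis and hypoxia genes were higher in 20 of 22, median 0.27, with Pgam1, Ldha and Pkm at 0.27 ± 0.07, 0.28 ± 0.08 and 0.31 ± 0.09. Camera at the preset correlation gave adjusted p of 3.6e-12, 7.5e-07 and 0.00027 for the 3 lists. The adjusted p was 0.53 with an estimated correlation for each of them. In C57B6 at early and late passage and mixed BL at early and late passage, the pair medians were 0.11, 1.08, 0.04 and 0.55 for cell cycle genes, -0.02, 0.78, 0.06 and 0.46 for repair genes, and 0.23, 0.47, 0.10 and 0.17 for glycolysis genes. Without the late mixed BL Smurf2-/- array the glycolysis call was lost (adjusted p = 0.0557).

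Genes downstream of TGF-beta and BMP signals and of p53 lay lower without Smurf2 in the fit over all pairs, but not in every pair. TGF-beta and Smad targets were lower in 20 of 24 members, median -0.25, among them Ccn2 at -0.68 ± 0.29 (SE) and the elastic fibre genes Eln and Lox at -0.34 ± 0.18 and -0.63 ± 0.37. BMP and Id targets were lower in 11 of 16, median -0.19, with the differentiation inhibitor gene Id2 at -0.96 ± 0.24, Atoh8 at -0.73 ± 0.17 and the ligand gene Bmp4 at -1.41 ± 0.47. For p53 targets 22 of 26 were lower, median -0.18, with Fas lowest in p, then Trp53inp1 and the antiproliferative gene Btg2 at -0.71 ± 0.17 and -0.72 ± 0.20. Camera gave adjusted p of 0.0056, 0.023 and 0.0024, and the adjusted p was 0.53 for all 3 with an estimated correlation. In C57B6 at early and late passage and mixed BL at early and late passage, the pair medians were 0.07, -0.71, -0.11 and -0.42 for TGF-beta targets, 0.12, -0.89, -0.08 and -0.31 for BMP targets, and -0.22, 0.30, -0.10 and -0.53 for p53 targets. The p53 call was lost without the late mixed BL Smurf2-/- array (adjusted p = 0.0789). The late C57B6 array of either genotype was needed for the TGF-beta call (adjusted p of 0.152 and 0.143 without the Smurf2-/- and the wild-type array), as it was for the BMP call (0.152 and 0.252), which was also lost without the late Smurf2-/- (0.0650) or the early wild-type (0.0694) mixed BL array.

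Camera called 5 further lists, the Y chromosome genes and 4 with small shifts. Cartilage and bone markers were lower in 10 of 11 members, median -0.13, with cartilage collagen Col2a1 at -2.13 ± 0.51 (SE). Their pair medians were -0.17 and 0.05 in C57B6 at early and late passage and -0.07 and -0.22 in mixed BL. Hox genes, skeletal muscle markers and neural and glial markers had medians of 0.09, 0.07 and 0.06, with Ncam1 at 1.00 ± 0.34 and Mef2c at 0.59 ± 0.25. The 3 measured Y chromosome genes had a median of 2.35. Camera adjusted p were 0.011, 0.038, 0.035, 0.041 and 7.8e-11, and with an estimated correlation the adjusted p were 0.53, 0.75, 0.53, 0.58 and 0.21. By fry's test of a shift in a single direction, only the Y list was called for genotype (adjusted p = 0.0019). Members called over all genes numbered 3, all in the Y list. Adjusted over the list alone, Fas (adjusted p = 0.0041), Fanca (adjusted p = 0.038) and the 3 Y genes were called. The count of called lists, 11, was 6 without the late C57B6 Smurf2-/- array. Cartilage was lost without the early C57B6 Smurf2-/- array (adjusted p = 0.0816), and the Hox, muscle and neural calls each without 4 or 5 of the 8 arrays, the early wild-type C57B6, early mixed BL Smurf2-/- and late C57B6 Smurf2-/- arrays among them for all 3.

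**Figure D2:**
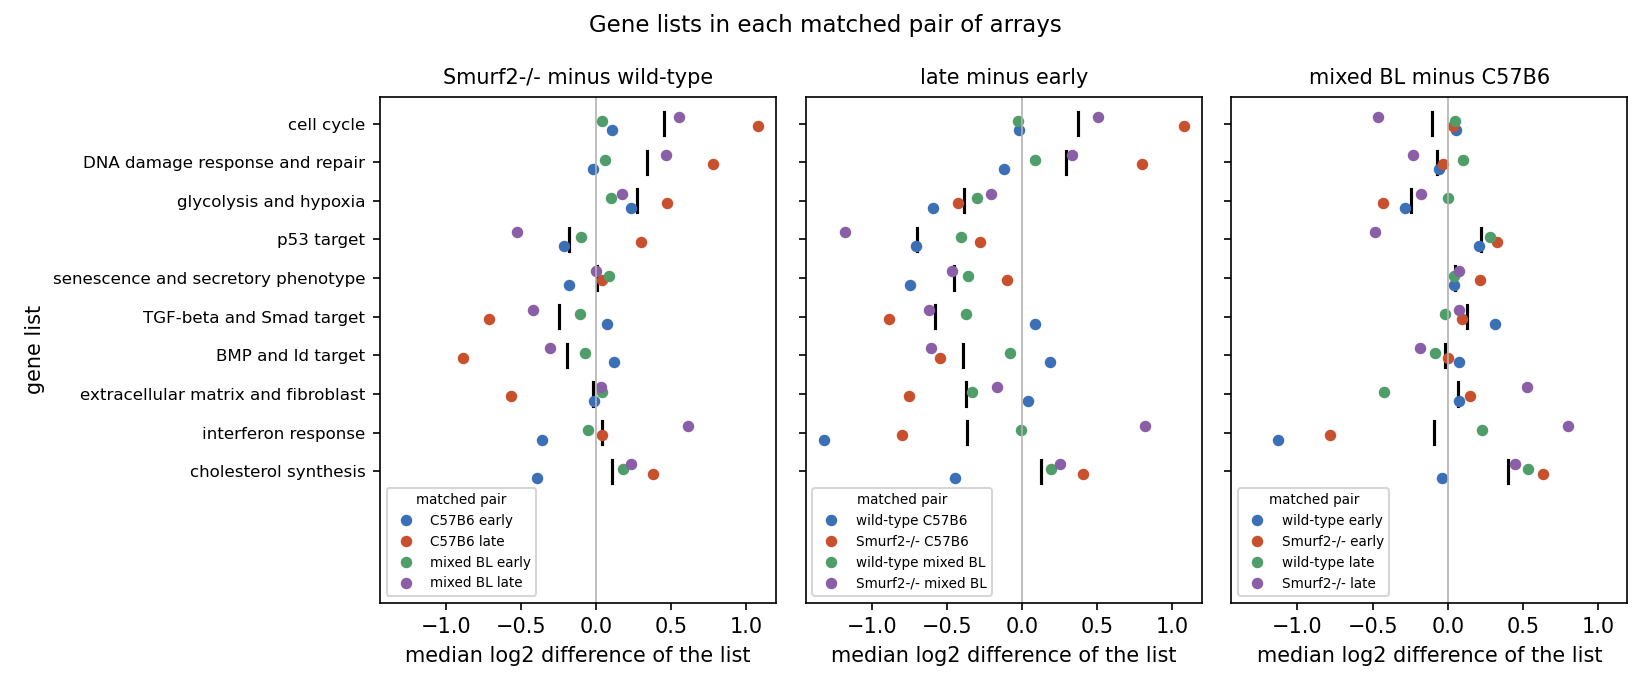
Median log2 difference of 10 gene lists in each matched pair of arrays for the 3 main comparisons; points are pairs and the black mark is the median of the fitted differences over all pairs. For Smurf2-/- minus wild-type, cell cycle genes lie at 1.08 and 0.55 in the late pairs and at 0.11 and 0.04 in the early pairs; for late minus early, p53 targets lie below 0 in all 4 pairs.

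Late passage was compared with early passage over both genotypes and backgrounds. Lrrc32, which presents latent TGF-beta at the cell surface, differed by -1.67 ± 0.12 (SE, n = 4 against 4), the trans-Golgi gene Tgoln1 by -0.96 ± 0.06 and the phosphatase gene Ptp4a3 by -0.80 ± 0.05. Also on the negative side were the protocadherin gene Pcdh9 at -1.32 ± 0.12, the protease inhibitor gene Serpinb8 at -1.12 ± 0.10, the ribosomal protein gene Rps4l at -0.90 ± 0.07, the actin bundling gene Pls3 at -0.85 ± 0.08 and the mechanosensitive channel gene Piezo1 at -0.56 ± 0.05. On the positive side were the G protein gene Gnao1 at 1.29 ± 0.13, the nuclear envelope gene Syne2 at 1.12 ± 0.13, Cdca7 at 1.07 ± 0.10, Rab39b at 0.86 ± 0.07, Septin6 at 0.69 ± 0.08, Rrad at 0.61 ± 0.07, Net1 at 0.56 ± 0.07 and the Polycomb gene Cbx2 at 0.46 ± 0.06. All had the same sign in 4 of 4 pairs, as the naming rule required.

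None of these passed as a cluster, with limma adjusted p from 0.0599 to 0.0864. Limma called 0 clusters for passage, with 4276 at an unadjusted p under 0.05, and 75 at an adjusted p under 0.1, of which 65 were lower. Over gene means Tgoln1, Ptp4a3 and Lrrc32 were called, each with an adjusted p of 0.0463 and 0 of 4 pairs higher. The count was 3 without the late C57B6 Smurf2-/- array and 2 without the late wild-type mixed BL array. With the planned trend in the fit it was 29 (3 higher, 26 lower), whereas the fit without a trend was adopted after seeing the data. Within wild-type and within Smurf2-/- cells limma called 0, with 1759 and 3480 clusters at an unadjusted p under 0.05. Across clusters, which are not independent replicates, the passage differences of wild-type and Smurf2-/- cells correlated with r = 0.45.

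Targets of p53 were lower at late passage in 22 of 26 members, with a median of -0.70. Over all genes 0 were called, and adjusted over the list alone 12 fell, each in 4 of 4 pairs. Among them were the apoptosis genes Pmaip1 (-1.36 ± 0.17, SE), Fas (-1.01 ± 0.11) and Eda2r (-1.25 ± 0.34), Btg2 (-1.12 ± 0.20), the cyclin Ccng1 (-0.99 ± 0.24), and Mdm2 (-1.01 ± 0.31), the p53 ubiquitin ligase. Senescence and secretory phenotype genes were lower in 21 of 26, median -0.45; 0 were called over all genes, and 9 fell when adjusted over the list alone. These included the metalloproteinase genes Mmp3 and Mmp13 (-2.32 ± 0.68 and -1.53 ± 0.37), the chemokines Ccl2 and Ccl7 (-1.98 ± 0.48 and -2.02 ± 0.41), Igfbp3 and Igfbp7 (-2.15 ± 0.57 and -1.10 ± 0.18), and Glb1, which encodes lysosomal beta-galactosidase (-0.54 ± 0.14). Camera adjusted p were 9.9e-08 and 1.2e-05, and the adjusted p was 0.48 for both with an estimated correlation.

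TGF-beta and Smad targets were lower at late passage in 23 of 24 members, median -0.58, with Ccn2 at -1.34 ± 0.29 (SE), Pmepa1 at -1.10 ± 0.35 and the inhibitory Smad gene Smad7 at -1.09 ± 0.35, none called over all genes or adjusted over the list alone; in wild-type C57B6 the list median was 0.08. Glycolysis and hypoxia genes were lower in 20 of 22, median -0.39; adjusted over the list alone Pgam1 (-0.58 ± 0.07), Ldha (-0.44 ± 0.08), Pkm (-0.46 ± 0.09), Aldoa (-0.36 ± 0.09) and the hypoxia-induced peptide gene Adm (-1.83 ± 0.42) fell, against 0 over all genes. Extracellular matrix and fibroblast genes were lower in 28 of 29, median -0.37, with Fbln2 at -0.82 ± 0.19 and Bgn at -0.53 ± 0.16. Fbln1 was higher at 0.81 ± 0.18. The matrix median was 0.04 in wild-type C57B6, -0.75 in Smurf2-/- C57B6, and -0.33 and -0.16 in wild-type and Smurf2-/- mixed BL. Camera adjusted p were 5.2e-06 for the first pair of lists and 0.00011 for the matrix list, with an estimated correlation adjusted p of 0.48, 0.48 and 0.60. The matrix call was lost without the late C57B6 Smurf2-/- array (adjusted p = 0.128).

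Hox genes, which set positional identity, had a median of -0.19 at late passage with 23 of 37 lower. The medians were -0.03 and -0.04 in wild-type and Smurf2-/- C57B6 and -0.32 and -0.29 in wild-type and Smurf2-/- mixed BL. Adjusted over the list alone 7 fell, against 0 over all genes, 5 of them in the Hoxc cluster: Hoxc8 (-2.53 ± 0.52, SE), Hoxc6 (-2.29 ± 0.43), Hoxc4 (-0.81 ± 0.20), Hoxc10 (-0.74 ± 0.19) and Hoxc9 (-0.68 ± 0.15), besides Hoxa9 and Hoxa6. Interferon response genes were lower in 18 of 24, median -0.36, with Lgals3bp at -1.68 ± 0.42, but the medians were -1.32 and -0.80 in wild-type and Smurf2-/- C57B6 and -0.0074 and 0.82 in wild-type and Smurf2-/- mixed BL. Cell cycle genes were higher in 30 of 34, median 0.37, with the licensing genes Mcm6 and Mcm7 both at 0.62, and DNA damage response and repair genes in 21 of 23, median 0.29. The cell cycle medians were 1.08 and 0.51 in Smurf2-/- C57B6 and mixed BL and -0.02 in wild-type cells of either background, and those of the repair genes 0.80 and 0.33 in Smurf2-/- and -0.12 and 0.09 in wild-type C57B6 and mixed BL. Camera adjusted p for the 4 lists were 0.0021, 0.035, 4.4e-05 and 0.00092, and 0.60, 0.70, 0.60 and 0.60 with an estimated correlation. The call of interferon response genes for passage was lost without any 1 of the 4 C57B6 arrays (adjusted p of 0.125 and 0.434 without the early and late Smurf2-/- array, 0.787 and 0.365 without the early and late wild-type array).

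The 2 backgrounds differed in 66 clusters by limma, 39 higher and 27 lower in mixed BL, which named 36 genes. Higher in mixed BL were the ribosomal protein gene Rps3a1 (2.07 ± 0.17, SE, n = 4 against 4), the splicing factor gene Cwc22 (1.87 ± 0.16, 3.65-fold), the synaptic gene Rims2 (1.48 ± 0.14), the mitochondrial ribosome gene Mrpl20 (1.35 ± 0.09) and the cadherin gene Cdh3 (1.20 ± 0.12). Commd6, Adat2, Cnot8, Nol10, Cox6a1, Fig4 and Ciapin1 were higher by 1.16 to 0.76. Lower in mixed BL were AI506816 (-4.41 ± 0.09, 21.2-fold), the noncoding RNA Gas5 (-2.01 ± 0.17, 4.03-fold), the ubiquitin ligase gene Trim13 (-1.95 ± 0.09), the phosphorylase kinase gene Phka2 (-1.68 ± 0.15), Atf7ip (-1.43 ± 0.12), the TNF receptor gene Tnfrsf1b (-1.40 ± 0.11), the complex I gene Ndufs5 (-1.31 ± 0.14), C1qtnf12 (-1.16 ± 0.08), the immediate early gene Egr1 (-1.12 ± 0.10) and the chaperone gene Hspa8 (-1.08 ± 0.10). Rcor2 and Pknox2 were lower at -0.95 ± 0.09 and -0.89 ± 0.10. Limma adjusted p ran from 0.000119 for AI506816 to 0.0452 for Pknox2. The same sign in 4 of 4 pairs was a condition of the naming rule. Whether the probes match both backgrounds equally is not known here, so not every difference need be one of expression. The clusters named Rps3a1, AI506816 and Cnot8 lie, by identifier, among clusters of genes on chromosomes 13, 1 and 8. The genes so named lie on chromosomes 3, 5 and 11, so what these clusters measure is not known here.

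Limma's count included 7 clusters of Cwc22 of nearly equal values, 5 clusters with several symbols and 19 with none; 3413 clusters had an unadjusted p under 0.05. The count was 252 without the late C57B6 Smurf2-/- array and between 1 and 4 without any other. It was 36 after quantile normalisation, 14 over gene means, 13 with all interactions and 398 with culture as a random block. In the last fit the culture correlation was estimated at -0.27, so arrays of a combination were treated as less alike than others. The rise to 398 therefore does not show that the background difference withstands shared cultures. With the planned trend it was 113, and among bright clusters, chosen after seeing the data, it was 27. AI506816 was called without each array in turn.

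Cholesterol synthesis genes were higher in mixed BL in 18 of 19 members, with a median of 0.40. The pair median was -0.04 in early wild-type arrays, against 0.535 in late wild-type and 0.63 and 0.45 in early and late Smurf2-/- arrays. Hsd17b7 rose by 0.59 ± 0.11 (SE, adjusted p = 0.034) adjusted over the list alone, against 0 members over all genes, and Mvd, Msmo1 and Lss stood at 0.49 ± 0.13, 0.44 ± 0.12 and 0.52 ± 0.17. Glycolysis and hypoxia genes were lower in 19 of 22, median -0.24, with Ldha at -0.38 ± 0.08, although Adm stood at 1.42 ± 0.42. Hox genes were higher in 28 of 37, median 0.09. Their pair medians were 0.31 and 0.07 in early and late wild-type arrays and 0.19 and -0.14 in early and late Smurf2-/- arrays. Camera adjusted p were 0.0001, 0.008 and 0.037, and 0.91 for all 3 with an estimated correlation. The glycolysis and Hox calls were lost without the early wild-type C57B6 array (adjusted p of 0.114 and 0.293) or the early mixed BL Smurf2-/- array (0.182 and 0.0983), and the Hox call without the early wild-type mixed BL array (0.187). The count of 3 called lists was 6 and 10 without the early Smurf2-/- and the late wild-type C57B6 array, 1 without the early wild-type C57B6 or early mixed BL Smurf2-/- array, and 5 without the late mixed BL Smurf2-/- array.

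Whether the genotype difference changed between early and late passage was tested as an interaction. Hspb1, a small heat shock protein gene, stood at -2.23 and -1.94 on the late Smurf2-/- arrays of C57B6 and mixed BL and between -0.63 and 0.58 on the other 6, an interaction of -3.00 ± 0.19 (SE). The transcription factor gene Mef2c stood at 0.90 and 1.10 on those late arrays and between -0.24 and 0.09 elsewhere, an interaction of 1.21 ± 0.12. Hmmr, a mitotic spindle gene, had an interaction of 1.18 ± 0.11 and D030056L22Rik of 1.15 ± 0.11; the Wnt antagonist gene Dact1 and S100a16 had -1.02 ± 0.12 and -1.17 ± 0.15. Limma called 0 clusters, with 1204 at an unadjusted p under 0.05, and the smallest adjusted p was 0.28, for Hspb1, which was lower without Smurf2 in both late pairs and higher in both early pairs.

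Cell cycle genes had a positive interaction in 34 of 34 members, with a median of 0.78. Over all genes 0 were called, and adjusted over the list alone 12 were, among them topoisomerase Top2a (1.09 ± 0.13, SE), cyclins Ccnb2 and Ccna2 (1.15 ± 0.27 and 1.14 ± 0.25), the transcription factor gene Foxm1 (1.00 ± 0.28) and the proliferation marker Mki67 (0.89 ± 0.25). DNA damage response and repair genes were positive in 22 of 23, median 0.58, with Rad54l (0.91 ± 0.17) and Fancd2 (1.27 ± 0.24) called over the list alone. BMP and Id targets were negative in 12 of 16, median -0.55; Id3 (-1.32 ± 0.23), Id2 (-1.07 ± 0.22), Smad6 (-1.07 ± 0.23), Atoh8 (-0.76 ± 0.16) and Bmp4 (-1.97 ± 0.51) were called when adjusted over the list alone and 0 over all genes. TGF-beta and Smad targets were negative in 21 of 24, median -0.68, with the contractile genes Cnn1, Tagln and Acta2 at -2.79 ± 0.72, -1.70 ± 0.51 and -0.95 ± 0.27. Camera adjusted p were 2.8e-21, 6.3e-13, 4e-06 and 2.8e-06; adjusted p were 0.38, 0.38, 0.32 and 0.34 with an estimated correlation. These 4 calls held without each array in turn.

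**Figure D3:**
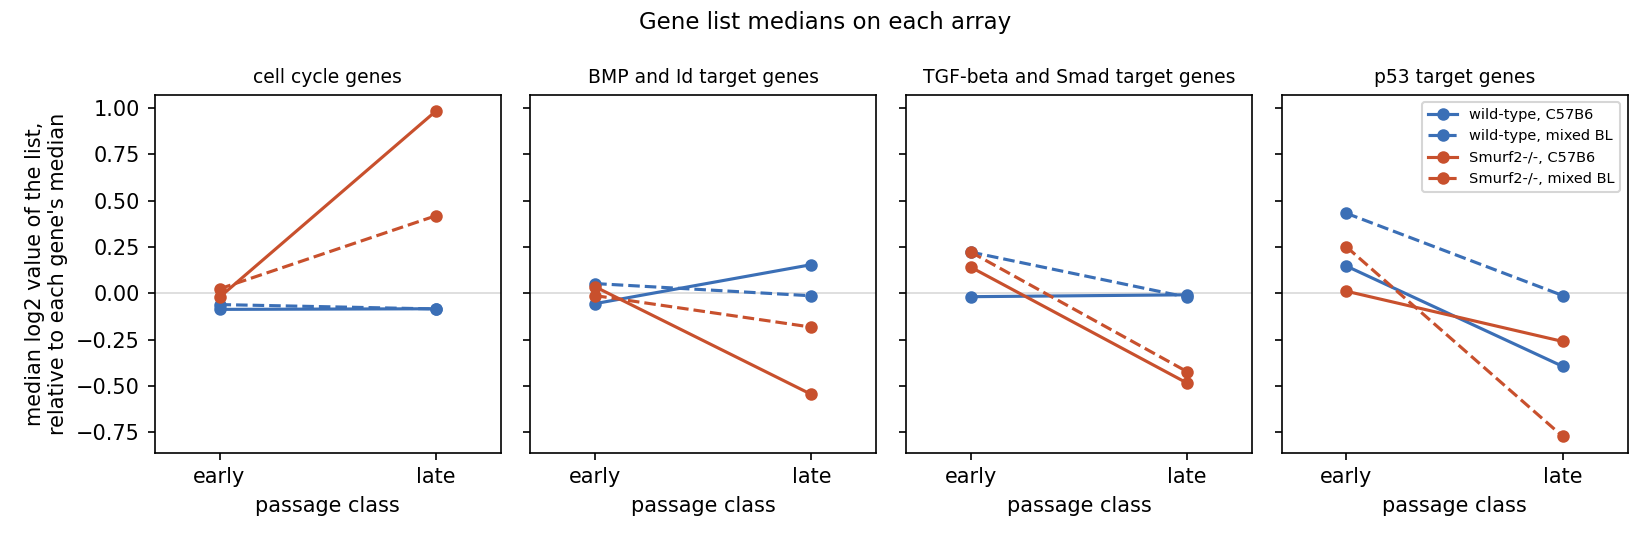
Median log2 value, relative to each gene's median over the 8 arrays, of 4 gene lists on each array at early and late passage; lines join arrays of the same genotype and background. Cell cycle genes stand at 0.98 and 0.42 on the late Smurf2-/- arrays of C57B6 and mixed BL and between -0.09 and 0.02 on the other 6.

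Camera also called cholesterol synthesis genes (median 0.43, 16 of 19 positive), interferon response genes (0.52, 23 of 24), extracellular matrix genes (-0.13, 19 of 29 negative) and the Y genes (-0.54, 3 of 3 negative) for this interaction. Adjusted p were 7.4e-05, 0.014, 0.028 and 0.028, and 0.74, 0.74, 0.74 and 0.64 with an estimated correlation. Leaving out late wild-type C57B6 lowered the count of called lists from 8 to 5. Either C57B6 wild-type array or either mixed BL Smurf2-/- array ended the interferon call, the interferon response genes for genotype by passage having a median from -0.071 to 1.07 without 1 array. The cholesterol call was lost without the early wild-type C57B6 or the late mixed BL Smurf2-/- array. The matrix call was lost without either late C57B6 array or either early mixed BL array, and the Y call without any 1 array other than the mixed BL Smurf2-/- arrays. Uty had an interaction of -0.54 ± 0.15 (SE), called over the list alone.

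Differences in the effect of genotype between backgrounds were tested in the same way. Xlr, an X-linked gene of a lymphocyte-regulated family, stood at 2.22 and 2.41 on the early and late C57B6 Smurf2-/- arrays and between -0.28 and 0.11 on the other 6, an interaction of -2.54 ± 0.19 (SE). The annexin gene Anxa8 stood at -1.07 and -2.15 on the same arrays, with an interaction of 2.07 ± 0.25, and the prolactin family gene Prl2c5 at 1.76 and 1.23 on the mixed BL Smurf2-/- arrays, with 1.51 ± 0.17. Taf1d and Zfp52 had interactions of 1.02 ± 0.13 and -0.92 ± 0.11, and Aif1l had a negative interaction of a similar size. Limma called 0 clusters, with 774 at an unadjusted p under 0.05 and a smallest adjusted p of 0.948. Over all clusters, which are not independent replicates, the genotype differences of the 2 backgrounds correlated with r = 0.27, and 0.25 without X and Y clusters.

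Extracellular matrix and fibroblast genes had a positive interaction with background in 24 of 29 members, with a median of 0.46. The growth factor receptor gene Pdgfra, at 3.99 ± 0.59 (SE), was called over the list alone and none over all genes; the collagen genes Col6a1, Col6a2 and Col6a3 stood at 1.15 ± 0.31, 1.00 ± 0.34 and 1.51 ± 0.44. Cholesterol synthesis genes were positive in 16 of 19, median 0.25, with Sqle (0.93 ± 0.15) called over the list alone, senescence genes in 19 of 26, median 0.32, and interferon response genes in 20 of 24, median 0.43. Camera adjusted p were 1.2e-06, 0.0027, 0.015 and 0.015, and 0.76, 0.90, 0.76 and 0.90 with an estimated correlation. The matrix call held without each array in turn. The others were each lost without 3 or 4 arrays, early wild-type C57B6 and early wild-type mixed BL in all 3. Medians of the interferon and cholesterol lists took either sign across the fits without 1 array. The count of 4 called lists was 8 without late wild-type C57B6, 1 without early and 7 without late wild-type mixed BL, and 2 after quantile normalisation.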

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

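Tests of the interactions, sex-linked genes, chromosomes, Smurf2's neighbours and other splits of the arrays were chosen before their results were seen. The fit without X and Y clusters was added after seeing the data. No bound was set beforehand for the split counts at an unadjusted p under 0.05.

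The genotype difference changed between early and late passage by camera's test of the interaction at the preset correlation. This held for cell cycle genes (median interaction 0.78), DNA damage response and repair genes (0.58), TGF-beta and Smad targets (-0.68) and BMP and Id targets (-0.55). It also held for cholesterol synthesis genes (0.43), interferon response genes (0.52), extracellular matrix genes (-0.13) and Y genes (-0.54). With an estimated correlation none was called, with adjusted p of 0.38, 0.38, 0.34, 0.32, 0.74, 0.74, 0.74 and 0.64. The genotype difference also varied between backgrounds, again at the preset correlation. The lists were senescence (median interaction 0.32), extracellular matrix (0.46), interferon response (0.43) and cholesterol synthesis genes (0.25). Camera adjusted p were 0.76, 0.76, 0.90 and 0.90 with an estimated correlation.

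The sex-linked genes differed between the genotypes in every pair. The X-linked genes Eif2s3x, Ddx3x, Kdm5c and Kdm6a, which escape silencing on the inactive X and so are higher in cells with 2 X chromosomes, were lower in Smurf2-/- by -0.35 ± 0.10, -0.40 ± 0.09, -0.32 ± 0.11 and -0.77 ± 0.19 (SE), each in 4 of 4 pairs. Their median, -0.38, lay at percentile 0.53 of 10000 random lists drawn from 569 X-linked genes. The values are consistent with wild-type cultures from female and Smurf2-/- cultures from male embryos, or from mixes in which these prevailed. Embryo sex and genotype then separate the same arrays, so a sex effect cannot be taken out of any genotype difference.

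Late and early wild-type C57B6 arrays differed most along chromosome 15, the pattern that a change in chromosome copy number in the culture would give. Over its 700 genes (membership from assembly GRCm38.p6) the median difference was 0.16, or 1.12-fold, with 0.18 and 0.15 in its proximal and distal parts, where random gene sets lay between -0.03 and 0.03. It was the 1 chromosome that met the bounds set beforehand in the 4 combinations of genotype and background. Of its 35 windows 100% lay on the same side, past the bound set against clusters of co-regulated neighbours as its source. This carries little weight, since the chromosome was picked for a shift of its median in both parts. Chromosomes 17 and 2 in wild-type C57B6, which did not meet the bounds, had 92.7% and 92.8% of windows on the shifted side. A change in copy number in part of the cells is a candidate explanation, if both arrays are passages of the same culture, which the labels do not say. It stays open because lying outside all random sets was common, for 13 of 20 chromosomes in wild-type C57B6, chromosome 15 included, and for 2, 5 and 6 in Smurf2-/- C57B6, wild-type mixed BL and Smurf2-/- mixed BL, with chromosomes 17 and 2 at 0.099 and 0.069 in wild-type C57B6, chromosome 6 at 0.083 in Smurf2-/- C57B6, and chromosome 15 at 0.050, 0.031 and 0.017 in wild-type mixed BL, Smurf2-/- mixed BL and Smurf2-/- C57B6.

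DNA around Smurf2 that came with the targeted allele from another strain could set genotype differences of its neighbours in C57B6. Of the 40 genes nearest Smurf2 on chromosome 11, the median size of the moderated t was 1.08 in C57B6, at percentile 80.4 of such windows (median 0.94), and 0.77 in mixed BL, at percentile 63.5. The neighbour with the strongest difference was Pitpnc1, at -0.83 ± 0.14 (SE). The percentile lay between the bounds set beforehand, so carried DNA and no carried DNA cannot be told apart here.

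All 33 ways of this kind to part the 8 arrays were compared. The splits treat the 8 arrays as exchangeable, although early and late arrays may be passages of the same culture. A share of 1 of 33, the smallest possible, therefore does not exclude chance between cultures. For genotype 1 of 33 splits, the real one, gave as many called clusters (3, highest other 1). Uty and Kdm5d are Y-linked, and the count is 0 without X and Y clusters. That count therefore does not stand apart from the separation by sex-linked genes. The cluster without a symbol, 10608138, was given no chromosome, so the fit without X and Y clusters kept it. By identifier it follows the clusters of the Y-linked genes Kdm5d (10607972), Eif2s3y (10608001) and Uty (10608107). Like them it was higher in Smurf2-/- in 4 of 4 pairs, so it may be Y-linked, which was not tested. The real split also gave the most called lists (11, 1 of 33, highest other 10), but the lead is 1 list, the Y list is among the 11 and the count is 0 with an estimated correlation, so this is not taken to exclude chance. At an unadjusted p under 0.05, however, 7 of 33 splits gave as many clusters as genotype's 1749, and the highest other gave 3964, which points to a structure of the samples: it parts the early C57B6 arrays, late wild-type C57B6 and late wild-type mixed BL from both late Smurf2-/- and both early mixed BL arrays. For background 1 of 33 gave as many clusters (66, highest other 1), as did 1 of 33 at an unadjusted p under 0.05 (3413, highest other 2844). By contrast 31 of 33 gave as many called lists (3, highest other 10). For passage the real count was 0 (highest other 0), which all 33 splits reach by construction, so that comparison says nothing. At an unadjusted p under 0.05, 1 of 33 splits gave as many clusters as passage (4276, highest other 2593). As many called lists came from 9 of 33 (9, highest other 11), so chance cannot be excluded for the list count.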

How the results depend on the processing

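The fits with bright clusters, with array medians at 0 and without X and Y clusters were chosen only after the data were seen. So was every alternative for passage within Smurf2-/- cells, and so was the reported fit without a trend. The others, the trend included, were planned. For genotype (3 called clusters) the count was 0 after quantile normalisation, 5 over gene means (3 higher, 2 lower), 0 with all interactions, 7 with culture as a random block (4 higher, 3 lower), 0 among bright clusters, 0 without X and Y clusters, and 0 to 2 without 1 array. The fit without the replicate block, which drops the pairing by passage class, called 5 (4 higher, 1 lower), among them all 3; for genotype in C57B6 it called 1 instead of 0, and it moved no other count of clusters by over 1.5 times. Passage (0) gave 3 over gene means, 29 with a trend, 3 among bright clusters and 0 to 3 without 1 array. Background (66) gave 36 after quantile normalisation (23 shared), 14 over gene means, 13 with all interactions (12 shared), 398 with culture as a random block (66 shared), 113 with a trend (66 shared), 27 among bright clusters (19 shared) and 1 to 252 without 1 array. Genotype at early passage (1) gave 0 after quantile normalisation, with culture as a random block, with a trend and among bright clusters, and 0 to 2 without 1 array; genotype in mixed BL gave 0 to 2. The culture correlation was estimated at -0.27. Being negative, it treats arrays of a combination as less alike than others. The higher counts with culture as a random block are therefore no guard against shared cultures.

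Lists called numbered 0 with an estimated correlation in all 5 comparisons. Among bright clusters there were 4 for genotype (11), 5 for its interaction with passage (8) and 2 for that with background (4), the last also 2 after quantile normalisation. Without 1 array there were 6 to 11 for genotype, 1 to 10 for background, 5 to 9 for the interaction with passage and 1 to 8 for that with background. The median of interferon response genes for genotype by passage was 0.010 among bright clusters, where camera's direction turned, and -0.071 to 1.07 without 1 array. Without 1 array, extracellular matrix and fibroblast genes for genotype by passage ran from -0.52 to -0.0031, and in the interaction with background interferon response genes ran from -0.24 to 1.04 and cholesterol synthesis genes from -0.15 to 0.56. The cause was not tested for any of these. The Smurf2 difference stayed negative, between -1.69 and -1.49 without 1 array and -1.46 after quantile normalisation. Culture could not be fitted as a random block with the interaction of genotype and background. The planned filters on dim clusters, set on the mean, were not run, since the mean of centred values is no level, and a fit without a filter or trend is the one reported. The list tests likewise took the mean of a gene's clusters in place of the planned cluster with the highest mean. The signal over background behind each value is unknown.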

Other observations

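No test in this part was chosen only after its result was seen. Imprinted genes, many of them regulators of fetal growth, were not called as a list by camera for genotype (19 measured, median -0.04, adjusted p = 0.15), passage (-0.05, 0.12) or background (-0.27, 0.13), and single members went both ways. By fry's test of change in either direction they were called for passage (adjusted p = 0.0041) and background (0.0105). Unlike camera, that test does not compare a list with other genes. For passage it called 11 of 25 lists, and 4276 clusters had an unadjusted p under 0.05 by limma. Its calls therefore do not show that the genes of a list changed more than others. With late passage Igf2r, the scavenger receptor for insulin-like growth factor 2, fell (-0.90 ± 0.09, SE), as did Impact (-0.65 ± 0.15), the growth inhibitor Cdkn1c (-1.14 ± 0.30) and Ndn (-2.15 ± 0.59), and Peg10 rose (1.14 ± 0.31), 5 genes adjusted over the list alone and 0 over all genes, each in 4 of 4 pairs. In mixed BL Igf2 was higher (2.04 ± 0.47) and Igf2r lower (-0.57 ± 0.09), both called over the list alone. Without Smurf2, Igf2, Plagl1 and Mest stood at -2.06 ± 0.47, -0.96 ± 0.28 and -2.75 ± 1.08 and Dlk1 at 1.76 ± 0.67, same sign in 4 of 4 pairs, none called. Oxidative stress (Nrf2) genes had a median of 0.09 for genotype (camera adjusted p = 0.32). Their medians were -0.03 for passage (0.75, with a positive mean and test) and 0.29 for background (0.13). Fry in either direction called them for passage (0.0048) and background (0.0105), again without comparing them with other genes. The cystine transporter gene Slc7a11 (1.33 ± 0.20) and Gstm1 (0.89 ± 0.14) rose with passage over the list alone, in 4 of 4 pairs, against 0 over all genes.

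H2B ubiquitination and chromatin modifier genes had a median of -0.04 for genotype (30 measured, camera adjusted p = 0.61, with a positive mean and a negative test). For passage the median was 0.10 (camera adjusted p = 0.18). Fry in either direction called the list for passage (0.0041), without comparing it with other genes. With passage Dpy30 (0.55 ± 0.11), Wdr5 (0.37 ± 0.08) and Usp22 (0.41 ± 0.09) rose over the list alone, in 4 of 4 pairs, and 0 over all genes; without Smurf2 the H2B ubiquitin-conjugating enzyme gene Ube2b stood at -0.23 ± 0.07 and the maintenance methylation genes Uhrf1 and Dnmt1 at 0.64 ± 0.26 and 0.39 ± 0.14. NEDD4 family ligase genes, the family of Smurf2, had a median of -0.12 for genotype (8 measured, 0.39), with Wwp2 at -0.75 ± 0.27 and Nedd4l at -0.71 ± 0.42. Wnt targets had a median of 0.07 (0.97, with a negative mean), and in the interaction with passage Lef1 (0.88 ± 0.19) and Nkd1 (-0.90 ± 0.16) were called over the list alone. Extracellular matrix, cholesterol synthesis, interferon response and senescence genes were not called for genotype, with medians of -0.02, 0.11, 0.04 and 0.01 and adjusted p of 0.39, 0.39, 0.91 and 0.89, the last with a negative mean and test.

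Besides the cartilage, muscle and neural markers called above, 5 lists of markers of other cell types were not called for genotype by camera: macrophages and leukocytes had a median of -0.01 (adjusted p = 0.61), endothelium 0.04 (0.40), epithelium and keratinocytes 0.04 (0.52), adipocytes 0.05 (0.89) and erythroid cells 0.07 (0.21). For passage their medians were -0.05, 0.08, 0.11, 0.08 and 0.06, with adjusted p of 0.12, 0.33, 0.14, 0.28 and 0.28 by camera. Fry in either direction, which compares no list with other genes, called the endothelial list for passage (0.048). In all, fry in either direction called 0 lists for genotype, 11 for passage, 2 for background, 3 for the interaction of genotype with passage and 0 for that with background. BMP and Id targets (0.0076) and skeletal muscle markers (0.034), which camera did not call for passage, were among the 11. The macrophage lysozyme gene Lyz2 stood at -1.72 ± 0.52 (SE) for passage, in 4 of 4 pairs, and at 1.29 ± 0.52 for background, and the endothelial genes Erg and Flt1 at -0.99 ± 0.40 and 0.68 ± 0.28 for genotype.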
